A study of Solanum lycopersicum with 18 samples.

How the data were processed

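Expression was measured on the Affymetrix tomato array in outer pericarp and epidermis of fruit of cv. Ailsa Craig. Per the labels, the 18 arrays form 6 groups of 3 biological replicates: healthy, wounded and Botrytis-inoculated fruit at the mature green and the red ripe stage. Each replicate was a pool of tissue from at least 5 fruit, and biotin-labelled cRNA was made from 10 µg of total RNA, per the labels' protocols.

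The deposited values are log2 probe set values, 1 per array, summarised and normalized by the authors with affy and RMA, per the submitters' processing notes, which give no version. They were used as deposited, without further normalization. Of the 10209 probe sets in the deposited table, 108 are controls and were kept out of every test, and 10101 were tested. Gene names come from the series' own probe annotation: 909 tested probe sets carry 1 symbol, 0 carry several and 9192 carry none. The symbols name 803 genes, 82 of them with more than 1 probe set, and 786 were found in the current RefSeq gene table. A gene is represented by its probe set with the highest mean over the 18 arrays.

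All 18 arrays entered 1 linear model with a coefficient per group, fitted with limma 3.58.1 (lmFit, contrasts.fit and eBayes with default settings) in R 4.3.3. There were 9 comparisons: inoculated against wounded, wounded against healthy and inoculated against healthy fruit at each stage, red ripe against mature green healthy fruit, and the difference between stages (red ripe minus mature green) of the inoculation and of the wounding change. P-values are those of limma's moderated test, two-sided, adjusted by the Benjamini-Hochberg method over the 10101 probe sets of a comparison. A probe set was called at an adjusted p under 0.05, and standard errors are those of the moderated model. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

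In all, 18 gene lists were fixed by symbol, synonym or description, but members were matched by symbol or synonym only. Of these 15 had measured members: pathogenesis-related proteins, jasmonate biosynthesis, wound- and jasmonate-inducible defence proteins, ethylene synthesis and perception, ERF and WRKY transcription factors, phenylpropanoid and lignin enzymes, carotenoid biosynthesis, cell wall disassembly, ripening regulators and markers, photosynthesis, redox and detoxification, heat shock proteins and chaperones, isoprenoid and sterol enzymes, sugar metabolism, and epidermis and cuticle. The other 3 (ribosomal proteins, genes conserved between plants and fungi, and seed and locular tissue) matched no gene name and were not analysed here. Lists share members: ACS2, ACS4, PG2 and Psy1, for example, belong to the ripening list and to another. The gene dad-1 matched the jasmonate list by a shared name only and was taken out. Each list was tested with limma's camera over the 803 genes at a preset correlation between genes of 0.01, adjusted over 126 list-by-comparison tests, with an estimated correlation as the alternative. The heat shock list has 2 members and was not tested. Counts of members use the adjusted p over all 10101 probe sets, and beside it the p adjusted over the list alone. The probe sets raised or lowered at least 2-fold between healthy mature green and red ripe fruit were tested as 2 further sets with camera.

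The comparisons, tests, lists, the rule for named genes and most alternatives were chosen before the data were examined. By that rule the text may name, for infection at each stage, the difference between these and ripening, the 8 largest rises and 8 largest falls among called genes whose replicates do not overlap, and up to 4 members of a list by smallest adjusted p. No overlap condition applies to differences between stages; 3 against 3 arrays fail to overlap by chance in 10% of cases. For the other comparisons the numbers are 3, 3 and 2. A fixed set of defence, ethylene and ripening genes (PR1b1, P4, CHI3, CHI9, LAPA1, CEVI57, loxD, AOS, ACS2, LOC544279, ETR4, E8, Psy1, PG2, EXP1, RIN and NOR) may be named anywhere. In all 142 genes with a LOC symbol and no synonym were passed over.

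Alternatives were the replicate number as a block, leaving out the lowest 25% of probe sets by mean, centring each array on its median, quantile normalization, a trended and robust prior, array weights, a fit on the compared groups alone, a 2-fold threshold, each array left out in turn, and other probe sets of a gene. On simulated data with 200 of 10101 probe sets changed, in the design of mature green infection, 60% of changes of log2 0.5, 92% of 1, 98% of -1 and 100% of 2 were recovered (50 each), and 5 unchanged probe sets were called. The simulated noise was independent between probe sets and of equal spread on all arrays, so these values need not hold for the real arrays. Labels that share a replicate number were not taken as pairs. The number of arrays limits the precision of all values.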

Results

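Fruit of tomato (Solanum lycopersicum cv. Ailsa Craig) were profiled at 2 stages, mature green at 31 days post anthesis and red ripe at 42 days post anthesis. At each stage fruit were left healthy, wounded and given 10 µL of water, or wounded and given 10 µL of water with 5000 conidia of Botrytis cinerea, the fungus that causes grey mould. Outer pericarp and epidermis around the inoculation sites were taken 24 h after inoculation, and healthy and wounded fruit were kept under the same conditions. RNA was hybridised to the Affymetrix tomato array. Each of the 6 groups held 3 arrays, 18 in all, and each biological replicate was a pool of at least 5 fruit, so p-values measure the spread between such pools. The number of arrays limits the precision of every value below. The log2 values covered 10101 probe sets besides 108 control probe sets, and 909 of the 10101 carried a gene symbol, for 803 genes.

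Arrays of one group correlated with each other at r = 0.994 to 0.998 over these probe sets, and array medians lay between 7.28 and 7.47. The lowest value on an array was 2.23 to 2.49 and the highest 13.60 to 13.93, and the size of a change is limited for genes near either end. The first principal component held 78.1% of the variance and parted mature green from red ripe fruit, and the second held 9.1% and parted healthy from wounded and inoculated fruit. The 25S rRNA control signal differed between groups. Its mean was 7.09 ± 0.09 (SD, n = 3, log2) in healthy, 9.53 ± 2.49 in wounded and 8.29 ± 2.08 in inoculated mature green fruit. In red ripe fruit it was 12.62 ± 0.89, 13.60 ± 0.05 and 13.65 ± 0.13. The 17S rRNA control signal was 5.08 ± 0.10, 6.49 ± 1.42 and 5.73 ± 0.92 in the mature green groups. It was 6.67 ± 0.93, 11.18 ± 1.81 and 11.31 ± 0.95 in the red ripe groups. The 3′ probe set of the control gene ef1a exceeded its 5′ probe set by 1.22 ± 0.03, 1.87 ± 0.26 and 1.62 ± 0.38 in mature green fruit. In red ripe fruit it exceeded it by 2.50 ± 0.58, 2.88 ± 0.29 and 2.91 ± 0.29, in the same order of groups. The difference for the control gene actin was also larger in red ripe fruit (0.677, 0.874 and 0.849) than in mature green fruit (0.018, 0.410 and 0.206). That for the control gene gapdh was 1.104, 1.073 and 1.063 in mature green fruit. In red ripe fruit it was 1.242, 0.605 and 0.474, and so did not follow ef1a.

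**Figure D1:**
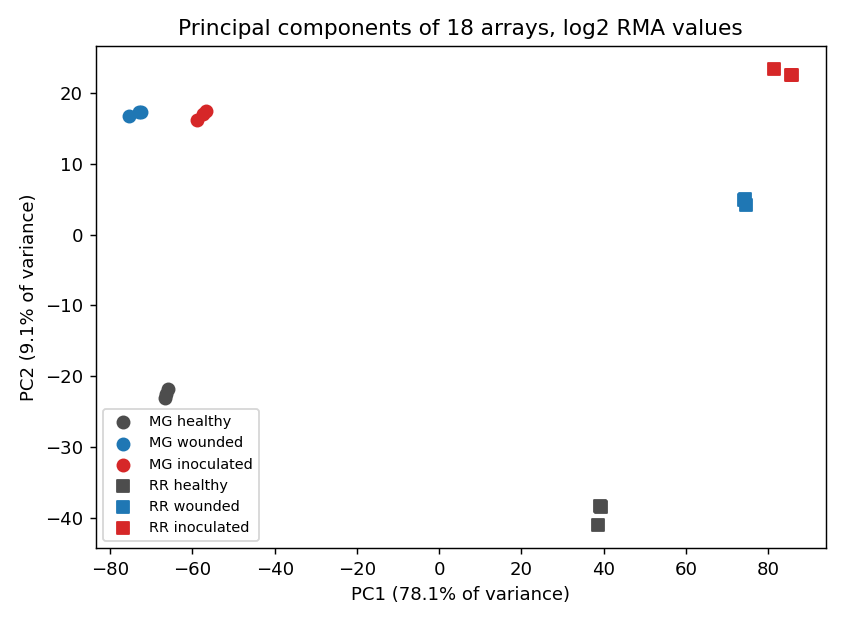
Scores of the 18 arrays on the first 2 principal components of the log2 values, with the percent of variance on each axis (78.1% and 9.1%). Circles are mature green and squares red ripe arrays, and colours give healthy, wounded and inoculated fruit; the 2 stages lie on opposite sides of 0 on the first axis.

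**Figure D2:**
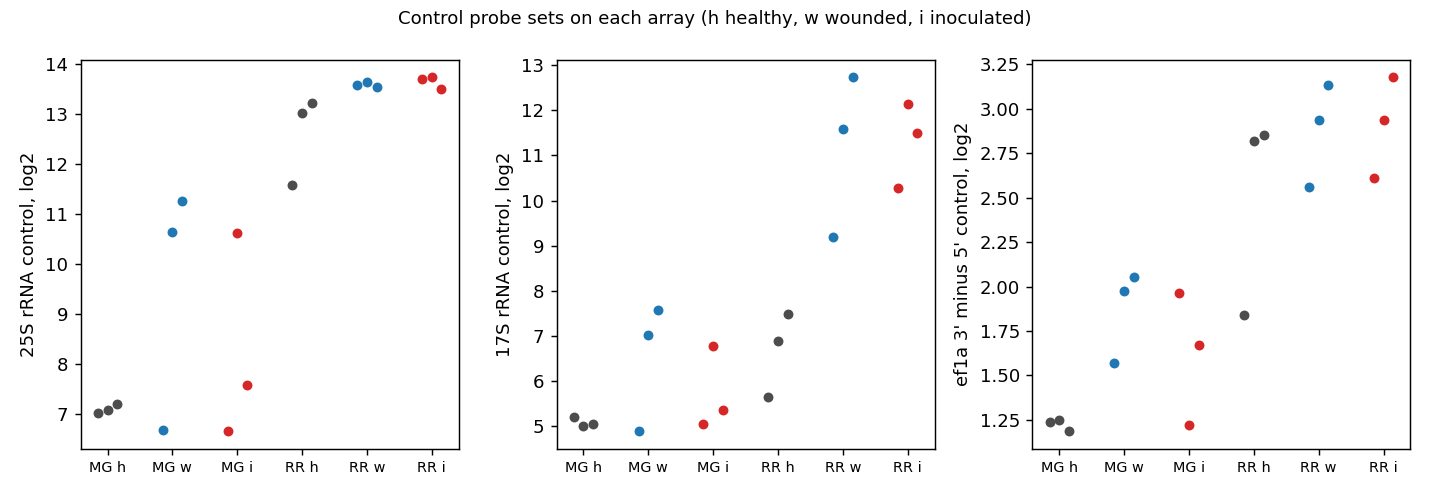
Log2 signal of the 25S and 17S rRNA control probe sets, and the log2 difference of the 3′ and 5′ control probe sets of ef1a, for each of the 18 arrays by group. Points are single arrays; the 25S signal lies near 7.09 in healthy mature green fruit and near 13.65 in inoculated red ripe fruit.

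The comparison of inoculated with wounded mature green fruit asks what the fungus adds to a wound at this stage. DES, which encodes a divinyl ether synthase of the lipoxygenase pathway, rose from 3.09 ± 0.12 (SD, n = 3) to 9.53 ± 0.03, a log2 change of 6.44 ± 0.16 (SE; adjusted p = 2.05e-14). Its level in wounded fruit lay near the lowest signal of the arrays. Further rises, given as log2 change ± SE, were those of cevi19, a fatty acid desaturase by its synonym SlFAD2-6 (4.76 ± 0.20), of the basic glucanase gene GluB (4.40 ± 0.09) and of PTI5, an ethylene response factor (3.49 ± 0.09). PG2, the polygalacturonase that degrades pectin in ripening fruit, rose by 3.46 ± 0.12, the mannanase gene Man4 by 3.38 ± 0.20, the proteinase inhibitor gene CEVI57 by 2.85 ± 0.15 and the basic chitinase gene CHI9 by 2.78 ± 0.09. The largest falls were in CHS2, a chalcone synthase of flavonoid synthesis (-2.46 ± 0.15), Dea1 (-2.06 ± 0.15), the endoglucanase gene cel7 (-1.96 ± 0.14) and the auxin response repressor IAA17 (-1.86 ± 0.15, with -0.50 and adjusted p = 0.0433 at its other probe set). They were followed by the ferric chelate reductase FRO1 (-1.69 ± 0.19), the endoglucanase cel5 (-1.51 ± 0.11), the phosphate starvation transcript TPSI1 (-1.50 ± 0.17) and the endoglucanase Cel2 (-1.47 ± 0.09).

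Of the 12 measured genes of pathogenesis-related proteins, which include chitinases and glucanases, 10 rose and 0 fell, and 10 and 0 adjusted over the list alone. The list as a whole was higher than other genes (camera adjusted p = 6.38e-05, and adjusted p = 0.0251 with an estimated correlation). LOC543878, with the synonym PR5, rose by 2.47 ± 0.12, the acidic chitinase gene CHI3 by 1.48 ± 0.07 and P4, of the PR-1 family, by 0.88 ± 0.16. PR1b1, also of the PR-1 family, rose by 1.43 ± 0.14, with 0.13 (adjusted p = 0.522) at its other probe set, whose mean level was 2.85. Among 12 genes of ERF and WRKY transcription factors, 9 rose and 1 fell, and 10 and 1 adjusted over the list alone (adjusted p = 0.000187, and adjusted p = 0.0251 with an estimated correlation). ERF2 rose by 1.63 ± 0.07 and LOC606712, with the synonym TERF1, by 1.48 ± 0.11. ERF2 had fallen by more than this on mature green wounding, where 1 of the 12 genes rose and 9 fell. Against healthy fruit the list did not pass (camera adjusted p = 0.562), with 3 up and 4 down.

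Ripening regulators and markers also rose in inoculated mature green fruit: 11 of 15 rose and 1 fell, and 11 and 3 adjusted over the list alone (adjusted p = 0.00101, and adjusted p = 0.0251 with an estimated correlation). NOR, a NAC transcription factor required for ripening, rose by 2.15 ± 0.16 and RIN, a MADS-box factor required for ripening, by 1.31 ± 0.12. ACS4 and ACS2, ACC synthases of the ethylene pathway, rose by 2.34 ± 0.10 and 1.27 ± 0.08. Psy1, the fruit phytoene synthase, rose by 0.80 ± 0.07, with 0.56 (adjusted p = 0.00146) and -0.10 (adjusted p = 0.672) at its other probe sets, the latter with a mean level of 4.18. E8 and the expansin gene EXP1 did not pass, at -0.24 ± 0.09 and -0.02 ± 0.09. Of 24 genes of ethylene synthesis and perception, 9 rose and 1 fell, and 9 and 2 adjusted over the list alone. That list passed with adjusted p = 0.0277, and had adjusted p = 0.313 with an estimated correlation. Its members included the ACC oxidase ACO5 (1.44 ± 0.09) and the receptors ETR6 (1.61 ± 0.07), ETR4 (0.91 ± 0.06) and LOC544279, the Never-ripe receptor ETR3 (0.91 ± 0.07). ACO5 and ETR6 had fallen on mature green wounding by a similar or larger amount. Among 8 photosynthesis genes 0 rose and 5 fell, and 0 and 7 adjusted over the list alone, with adjusted p = 0.0129, and adjusted p = 0.313 with an estimated correlation. The chlorophyll a/b binding protein genes CAB5 and CAB4 fell, by 1.18 ± 0.14 and 0.56 ± 0.08. Of 23 genes of cell wall disassembly 2 rose and 12 fell, and 2 and 12 adjusted over the list alone, and the list did not pass (adjusted p = 0.0532). The 2 that rose were PG2 and Man4. Of 15 carotenoid genes 2 rose and 7 fell, and 3 and 8 adjusted over the list alone (adjusted p = 0.275). Against healthy in place of wounded fruit the ripening list did not pass, with 4 of 15 up and 8 down (adjusted p = 0.275; 12 of 15 had fallen on wounding), and the calls of the ERF and WRKY (adjusted p = 0.562), ethylene (adjusted p = 0.228) and photosynthesis lists (adjusted p = 0.328) ended as well.

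In all, 1971 of 10101 probe sets passed at an adjusted p under 0.05 by limma, 884 higher and 1087 lower, and 310 of them changed at least 2-fold, 204 up and 106 down. The rRNA control signals varied within both groups. Without the 3 mature green arrays of a 25S signal above 10, an alternative chosen after seeing the data, 791 probe sets passed, 450 higher and 341 lower. That leaves 1 wounded array, assumed to vary like the other groups; with array weights 3424 passed.

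**Figure D3:**
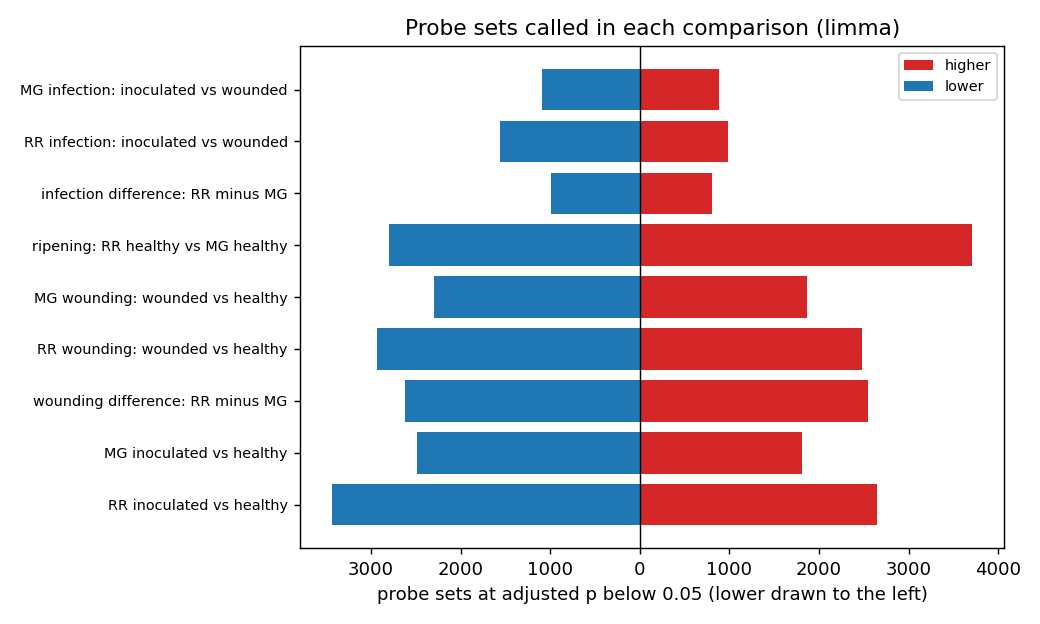
Number of probe sets called at an adjusted p under 0.05 in each of the 9 comparisons, of 10101 tested, with higher counts drawn to the right of 0 and lower counts to the left. Bars of mature green infection reach 884 and 1087, and those of ripening 3710 and 2793.

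The same comparison in red ripe fruit asks what the fungus adds to a wound in ripe tissue. ODC, ornithine decarboxylase of polyamine synthesis, rose from 5.85 ± 0.13 (SD, n = 3) to 10.29 ± 0.13, a log2 change of 4.44 ± 0.09 (SE; adjusted p = 1.14e-14) or 21.7-fold. CEVI57 rose by 4.20 ± 0.15, DES by 4.05 ± 0.16, the peroxidase gene CEVI-1 by 3.22 ± 0.13, the subtilisin-like protease gene sbt3 by 3.21 ± 0.14 and Dea1 by 3.11 ± 0.15. On red ripe wounding sbt3 had fallen by more than this rise. The cell wall invertase gene Wiv-1 rose by 3.05 ± 0.08 and the hexose transporter gene HT1 by 2.62 ± 0.11. The largest falls were in CHS2 (-3.07 ± 0.15), the tonoplast aquaporin TIP (-2.05 ± 0.11), the ribonuclease RNALE (-1.66 ± 0.08) and the lipid transfer protein TSW12 (-1.50 ± 0.22). Further falls were in the endoglucanase CEL8 (-1.44 ± 0.09), the inositol monophosphatase IMP1 (-1.33 ± 0.09), ACS4 (-1.30 ± 0.10) and the phospholipase PLDa3 (-1.27 ± 0.07).

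Among pathogenesis-related proteins 6 of 12 rose and 0 fell, and 6 and 1 adjusted over the list alone (adjusted p = 0.0266, and adjusted p = 0.208 with an estimated correlation). TSI-1 rose by 2.42 ± 0.15, LOC543878 by 1.35 ± 0.12, GluB by 1.04 ± 0.09 and PR1b1 by 1.23 ± 0.14, with 0.22 (adjusted p = 0.183) at the other PR1b1 probe set. On red ripe wounding TSI-1 and PR1b1 had fallen by more than these rises, so both stayed below healthy fruit. CHI3 and P4 did not pass, at -0.16 ± 0.07 and -0.02 ± 0.16. Of the ERF and WRKY genes 6 of 12 rose and 1 fell, and 7 and 1 adjusted over the list alone (adjusted p = 0.0159, and adjusted p = 0.0834 with an estimated correlation). EREB, with the synonym TSRF1, rose by 1.81 ± 0.14, PTI6 by 0.85 ± 0.09 and PTI5 by 0.52 ± 0.09. ERF3 rose by 0.57 ± 0.07 at one probe set and fell by 0.49 at another (adjusted p = 0.012).

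Carotenoid genes moved down in inoculated red ripe fruit: 0 of 15 rose and 9 fell, and 0 and 9 adjusted over the list alone (adjusted p = 0.0159, and adjusted p = 0.109 with an estimated correlation). They included the carotene hydroxylase CrtR-b1 (-0.46 ± 0.06) and the desaturases ZDS (-0.56 ± 0.08) and PDS (-0.39 ± 0.07). Of the 3 Psy1 probe sets 2 fell, by 0.24 (adjusted p = 0.0135) and 0.51 (adjusted p = 0.00295), and 1 rose, by 0.41 (adjusted p = 0.0273). All 3 epidermis and cuticle genes, which encode lipid transfer proteins, fell, also when adjusted over the list alone, ltpg1 by 1.13 ± 0.10 and LE16 by 0.36 ± 0.09 (adjusted p = 0.045, and adjusted p = 0.313 with an estimated correlation). That call ended with the replicate number as a block (adjusted p = 0.0512) and against healthy fruit (adjusted p = 0.381), as did that of pathogenesis-related proteins against healthy fruit (adjusted p = 0.834). Of the ripening regulators and markers 0 rose and 7 of 15 fell, and 0 and 7 adjusted over the list alone, and the list did not pass (adjusted p = 0.0967). NOR fell by 0.79 ± 0.16 and the MADS-box gene TAGL1 by 0.71 ± 0.08. PG2 was at -0.05 ± 0.12 and RIN at 0.05 ± 0.12, neither past the test. Among the ethylene genes 4 of 24 rose and 6 fell, and 4 and 7 adjusted over the list alone (adjusted p = 0.349). The ACC synthase ACS6 rose by 1.32 ± 0.07 and the ACC oxidase ACO4 fell by 1.23 ± 0.08. Of 23 cell wall genes 4 rose and 10 fell, and 4 and 11 adjusted over the list alone (adjusted p = 0.0967), with the galactosidase genes TBG3 at -1.23 ± 0.09 and TBG2 at -0.84 ± 0.07. Among 8 photosynthesis genes 0 rose and 5 fell, also when adjusted over the list alone (adjusted p = 0.267).

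Of 10101 probe sets 2547 passed in red ripe infection, 987 higher and 1560 lower, and 239 changed at least 2-fold, 187 up and 52 down. Centring each array on its median gave 1146 higher and 1131 lower, a share of 50.3% higher against 38.8%, and a fit on the 6 compared arrays alone called 1594.

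**Figure D4:**
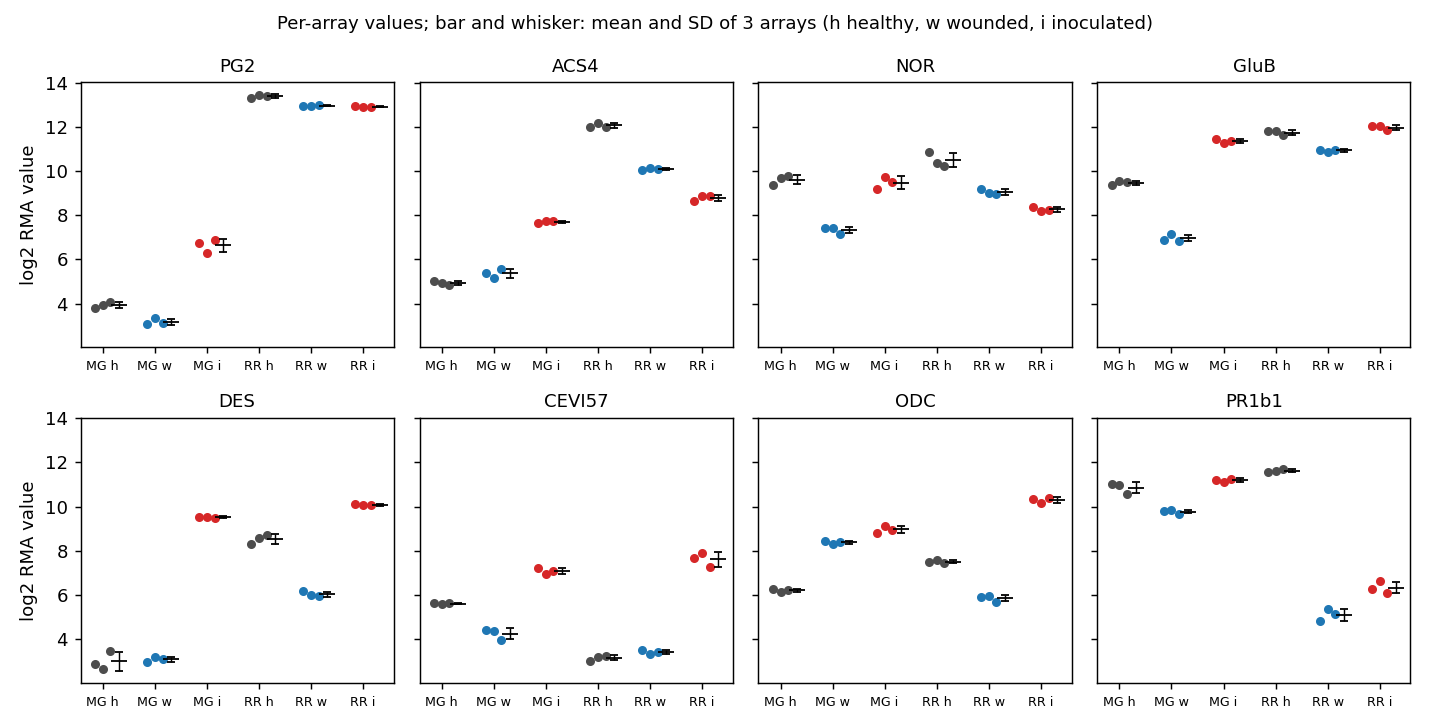
Log2 RMA value of 8 genes on each of the 18 arrays by stage and treatment; points are arrays, and bars and whiskers the mean and SD of 3 arrays. In mature green fruit DES rises from 3.09 in wounded to 9.53 in inoculated fruit, and PR1b1 falls from 11.63 in healthy to 5.10 in wounded red ripe fruit.

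Whether the response to inoculation differed between stages was tested as the red ripe change minus the mature green change. Dea1 fell on infection of mature green fruit and rose in red ripe fruit, a difference of 5.17 ± 0.22 (SE; n = 3 arrays in each of 4 groups; adjusted p = 5.70e-11). Changes were also higher in red ripe fruit for ODC (3.85 ± 0.13), sbt3 (2.54 ± 0.19), Wfi1, an NADPH oxidase that forms reactive oxygen (2.44 ± 0.16), psi14A (2.21 ± 0.26), HT1 (2.08 ± 0.15), cel7 (2.03 ± 0.19) and TSI-1 (1.95 ± 0.21). They were lower in red ripe fruit for Man4 (-3.90 ± 0.29), ACS4 (-3.64 ± 0.14), PG2 (-3.50 ± 0.16), TIP (-3.43 ± 0.15), GluB (-3.36 ± 0.12), cevi19 (-3.23 ± 0.28), PTI5 (-2.97 ± 0.13) and NOR (-2.93 ± 0.23). Of these genes sbt3 and TSI-1 had fallen on red ripe wounding by more than they rose on inoculation. GluB and NOR had fallen on mature green wounding.

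The ripening regulators and markers differed as a list between stages, with 1 of 15 genes higher and 10 lower in the red ripe response, and 1 and 12 adjusted over the list alone (adjusted p = 9.64e-05, and adjusted p = 0.0251 with an estimated correlation). RIN differed by -1.26 ± 0.17 and ACS2 by -1.28 ± 0.11. PG2 already stood at 12.97 ± 0.03 (SD, n = 3) in wounded red ripe fruit and at 12.92 ± 0.03 in inoculated fruit, against 3.19 ± 0.14 and 6.65 ± 0.29 in mature green fruit. The red ripe levels lay near the highest signal of the arrays, which leaves little room for a rise, and the size of the PG2 difference between stages depends on that range. Of the ethylene genes 2 of 24 were higher and 11 lower, and 3 and 11 adjusted over the list alone (adjusted p = 0.0159, and adjusted p = 0.312 with an estimated correlation). ETR6 differed by -1.97 ± 0.10, ACO4 by -1.76 ± 0.12 and ACS6 by 1.51 ± 0.10. Among pathogenesis-related proteins 1 of 12 was higher and 6 were lower, also when adjusted over the list alone (adjusted p = 0.0188, and adjusted p = 0.178 with an estimated correlation), with CHI9 at -2.13 ± 0.12 and CHI3 at -1.64 ± 0.10. PR1b1 gave -0.21 ± 0.20 and did not pass. Of the ERF and WRKY genes 1 of 12 was higher and 5 were lower, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.0919). Of 23 cell wall genes 5 were higher and 5 lower, and 9 and 6 adjusted over the list alone (adjusted p = 0.725).

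The difference passed at 1804 of 10101 probe sets, 809 higher and 995 lower, and was at least 2-fold at 448. With each array centred on its median 914 were higher and 771 lower, and of those at least 2-fold 243 were higher and 205 lower, so the majority depends on scaling and threshold. Without the 3 mature green arrays of a 25S signal above 10, chosen after seeing the data, 878 passed, with 1 wounded mature green array left and assumed to vary like the other groups. Against healthy fruit the calls of the ripening (adjusted p = 0.645) and ethylene lists (adjusted p = 0.813) ended.

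Red ripe was compared with mature green fruit in healthy tissue to describe ripening itself. PG2 rose from 3.93 ± 0.14 (SD, n = 3) to 13.40 ± 0.08, a log2 change of 9.47 ± 0.12 (SE; adjusted p = 7.91e-19), between levels near the lowest and the highest signal of the arrays, so its size depends on that range. ACS4 rose by 7.12 ± 0.10. PTI5 rose by 6.12 ± 0.09, the hexose transporter gene HT2 by 6.06 ± 0.09, the glutathione transferase gene ctu1 by 5.94 ± 0.19, DES by 5.53 ± 0.16, Wiv-1 by 5.29 ± 0.08 and the NAC factor NAC1 by 5.28 ± 0.07. The largest falls were in TSW12 (-7.69 ± 0.22), the lipoxygenase LOX1.1 (-6.88 ± 0.16) and the arginase ARG2 (-6.84 ± 0.18, with -6.56 and -1.80 at its other probe sets). They were followed by ltpg1 (-6.65 ± 0.10), GP1, the beta subunit of polygalacturonase (-6.64 ± 0.20), the inositol phosphate synthase LOC543809 (-6.48 ± 0.13), the xyloglucan endotransglycosylase XET2 (-6.44 ± 0.12) and CAB6A (-6.31 ± 0.13).

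Of the ripening regulators and markers 11 of 15 rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.0236, and adjusted p = 0.0955 with an estimated correlation). ACS2 rose by 4.97 ± 0.08, RIN by 3.93 ± 0.12, Psy1 by 1.14 ± 0.07 (1.60 and 0.44 at its other probe sets) and NOR by 0.87 ± 0.16, while E8 gave 0.10 ± 0.09 and did not pass. All 8 photosynthesis genes fell, also when adjusted over the list alone (adjusted p = 0.000131, and adjusted p = 0.144 with an estimated correlation), among them CAB4 (-4.27 ± 0.08), CAB5 (-4.64 ± 0.14) and LOC543978, the photosystem subunit PsaD (-3.19 ± 0.09). Of the pathogenesis-related proteins 11 of 12 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.00483, and adjusted p = 0.0955 with an estimated correlation), with LOC543878 at 3.74 ± 0.12 and CHI3 at 2.17 ± 0.07. The 3 lipid transfer protein genes of the epidermis list fell, also when adjusted over the list alone (adjusted p = 0.01, and adjusted p = 0.213 with an estimated correlation). Of the carotenoid genes 6 of 15 rose and 8 fell, also when adjusted over the list alone (adjusted p = 0.482). The plastid terminal oxidase PTOX rose by 1.41 ± 0.08 and the lycopene cyclase LCY1 fell by 2.46 ± 0.15. Of 24 ethylene genes 15 rose and 6 fell, also when adjusted over the list alone (adjusted p = 0.238). Of 23 cell wall genes 10 rose and 5 fell, also when adjusted over the list alone (adjusted p = 0.643). ERF and WRKY genes went both ways, 5 of 12 up and 5 down, also when adjusted over the list alone (adjusted p = 0.907). The 25S control signal was 5.53 higher and the 17S signal 1.59 higher in healthy red ripe than in healthy mature green fruit, alongside these groups.

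In all 6503 of 10101 probe sets passed, 3710 higher and 2793 lower, and 2014 changed at least 2-fold, 872 up and 1142 down. The median change over all probe sets was 0.104.

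The 872 probe sets raised and the 1142 lowered at least 2-fold on ripening were then followed through infection, which uses no array of the ripening comparison. These sets were chosen on this series, so they are not independent evidence of a direction in ripening. In mature green infection 368 of the raised set rose and 45 fell, and the set lay 0.496 above the other probe sets in mean log2 change (camera p = 8.8e-28, and p = 1.07e-06 with an estimated correlation). Of the lowered set 71 rose and 424 fell, a mean difference of -0.301 (p = 4.1e-14, and p = 0.00035 with an estimated correlation). The size for the raised set depends on its choice and on the reference: 0.217 without a fold threshold, 0.969 for the 200 most changed probe sets and 0.824 against healthy fruit, whose mature green arrays also chose the set. In red ripe infection the raised set differed by 0.208 (p = 1.41e-06, and p = 0.00184 with an estimated correlation) and the lowered set by -0.094 (p = 0.0549). The stages differed in this by limma's camera: the red ripe minus mature green difference was -0.288 for the raised set (p = 9.55e-07, and p = 0.00164 with an estimated correlation) and 0.207 for the lowered set (p = 1.75e-05, and p = 0.0161). By their choice the raised set stands nearer the highest signal, and the lowered set nearer the lowest, in healthy red ripe than in healthy mature green fruit. The signal range may therefore add to both values, as for PG2. It may likewise add to the 0.496 and -0.301 of mature green infection. Neither was tested, and no sets of matched signal level were compared. In mature green wounding, which shares the healthy mature green arrays with the sets, the raised set lay 0.328 above the others (limma camera p = 4.35e-06, and p = 0.00259 with an estimated correlation) and the lowered set 0.030 (p = 0.211). With those arrays parted in 6 ways, so that none both chose the set and served as reference, a check chosen after seeing the data, the raised set lay 0.278 to 0.311 above the others on wounding and 0.769 to 0.802 on inoculation against healthy fruit. In red ripe wounding, which shares the healthy red ripe arrays with the sets, the values were 0.255 (limma camera p = 0.000524) and -0.237 (p = 0.00142, and p = 0.0599 with an estimated correlation). The raised set thus lay above the others in infection and in wounding at both stages, and not only in mature green infection.

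Across probe sets, which are not independent replicates, the ripening and mature green infection changes correlated at r = 0.433 (Spearman 0.319). Both rose at 634 probe sets, where independent lists would share 324.7, and both fell at 695, where independent lists would share 300.6. Infection changes at the 2 stages, which share no arrays, correlated at r = 0.318 (Spearman 0.180), with 334 probe sets higher in both (independent lists, 86.4) and 344 lower in both (167.9). With the sets taken from wounded red ripe against wounded mature green fruit and followed in inoculated against healthy mature green fruit, a check chosen after seeing the data, the values were 0.171 and 0.114. Neither passed by limma's camera and the lowered set changed sign. The mature green wound change enters that choice and the followed change with opposite signs, so the check cannot decide whether ripening genes moved.

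**Figure D5:**
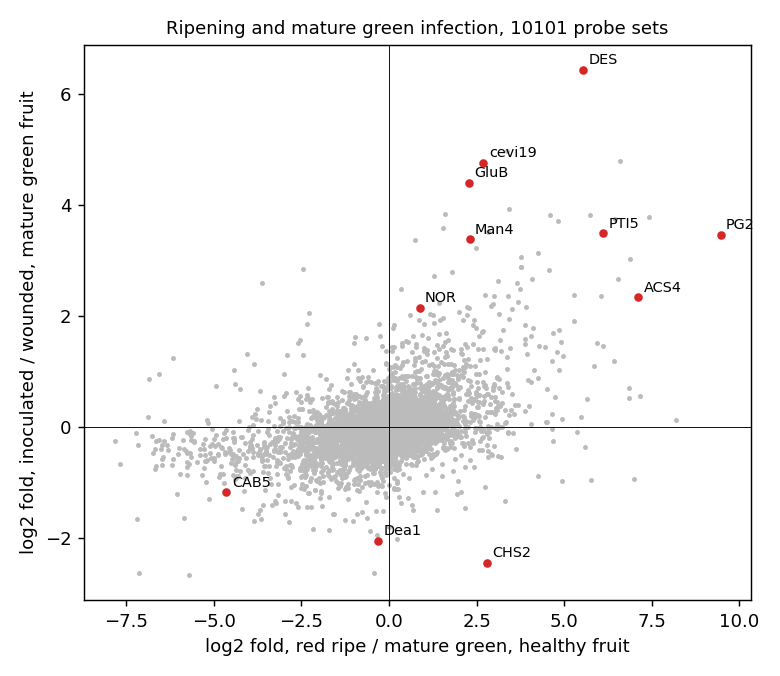
Log2 change on ripening in healthy fruit (x axis) against log2 change on infection of mature green fruit (y axis) for 10101 probe sets, with named genes in red. The correlation across probe sets is 0.433; PG2 lies at 9.47 and 3.46.

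Wounded and healthy mature green fruit were compared to describe the wound response itself. XTH6, a xyloglucan endotransglucosylase, rose from 3.66 ± 0.34 (SD, n = 3) to 9.94 ± 0.11, a log2 change of 6.28 ± 0.17 (SE; adjusted p = 1.85e-14), the expansin gene exp11 by 6.16 ± 0.14 and the endoglucanase gene cel5 by 5.30 ± 0.11. ACO5 fell by 2.67 ± 0.09, GluB by 2.50 ± 0.09 and NOR by 2.29 ± 0.16. Of the ripening regulators and markers 2 of 15 rose and 12 fell, also when adjusted over the list alone (adjusted p = 0.000486, and adjusted p = 0.0251 with an estimated correlation), among them MADS1 (-1.39 ± 0.09) and RIN (-0.73 ± 0.12). Psy1 fell by 1.12 ± 0.07, and its other probe sets gave -1.31 (adjusted p = 7.66e-08) and 0.09 (adjusted p = 0.633). Of the ERF and WRKY genes 1 of 12 rose and 9 fell, and 1 and 10 adjusted over the list alone (adjusted p = 0.00333, and adjusted p = 0.0389 with an estimated correlation). ERF2 fell by 2.24 ± 0.07, and the gene that rose was PTI5 (2.22 ± 0.09). Of 24 ethylene genes 3 rose and 12 fell, also when adjusted over the list alone (adjusted p = 0.00916, and adjusted p = 0.248 with an estimated correlation), with ETR6 at -1.68 ± 0.07. Of 23 cell wall genes 14 rose and 5 fell, and 14 and 6 adjusted over the list alone, and the list did not pass (adjusted p = 0.0736), with Cel2 at 3.75 ± 0.09 and the galactosidase TBG6 at 2.77 ± 0.10. Pathogenesis-related proteins went both ways, 6 of 12 up and 6 down, also when adjusted over the list alone (adjusted p = 0.941). The chitinase CHI17 rose by 2.43 ± 0.07 and PR1b1 fell by 1.09 ± 0.14, with 0.005 (adjusted p = 0.977) at its other probe set.

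A total of 4168 probe sets passed in mature green wounding, 1870 higher and 2298 lower, 630 of them at least 2-fold, 430 up and 200 down. The 25S control signal was 7.09 ± 0.09 in healthy and 9.53 ± 2.49 in wounded fruit (SD, n = 3). Without the 3 mature green arrays of a 25S signal above 10, an alternative chosen after seeing the data, 2321 passed, 1198 higher and 1123 lower, from 1 wounded array that is assumed to vary like the other groups.

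In red ripe fruit, wounding gave its largest rises in RNALE, from 5.94 ± 0.12 (SD, n = 3) to 10.77 ± 0.03, a log2 change of 4.83 ± 0.08 (SE; adjusted p = 2.09e-16), in ACS6 (3.54 ± 0.07) and in LOC543602, with the synonym Eli3 (3.30 ± 0.09, and 0.61 at its other probe set, of mean level 3.61). PR1b1 fell by 6.52 ± 0.14, or 92-fold, at its bright probe set, and its other probe set, with a mean level of 2.85, gave -0.22 (adjusted p = 0.119). The protease gene sbt3 fell by 4.73 ± 0.14 and TSI-1 by 4.43 ± 0.15. As a list the pathogenesis-related proteins did not pass, with 2 of 12 up and 6 down, also when adjusted over the list alone (adjusted p = 0.474). Of the ERF and WRKY genes 8 of 12 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.0138, and adjusted p = 0.08 with an estimated correlation), with WRKYIId-1 at 3.28 ± 0.07 and PTI4 at 1.88 ± 0.07. The jasmonate genes AOS, an allene oxide synthase, and loxD, a lipoxygenase, rose by 2.91 ± 0.11 and 2.45 ± 0.11. The 3 lipid transfer protein genes of the epidermis list rose, also when adjusted over the list alone (adjusted p = 0.0446, and adjusted p = 0.313 with an estimated correlation), a call that ended when each array was centred on its median (adjusted p = 0.0574). Of the carotenoid genes 2 of 15 rose and 9 fell, also when adjusted over the list alone (adjusted p = 0.132), with the plastid isoprenoid gene DXS at -1.68 ± 0.06. The 17S control signal was 6.67 ± 0.93 in healthy and 11.18 ± 1.81 in wounded red ripe fruit (SD, n = 3), alongside these groups.

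In red ripe wounding 5412 probe sets passed, 2484 higher and 2928 lower, and 1054 changed at least 2-fold, 542 up and 512 down. Centring each array on its median turned the majority, to 2873 higher and 2605 lower. Among these the invertase gene lin5 fell by 3.43 ± 0.13 and ACS4 by 1.97 ± 0.10.

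The wound response differed between stages, tested as red ripe minus mature green. WRKYIId-1 fell in mature green and rose in red ripe fruit, a difference of 4.20 ± 0.10 (SE; n = 3 arrays in each of 4 groups; adjusted p = 2.23e-14), with ACS6 at 3.56 ± 0.10 and ACO5 at 3.24 ± 0.13. TSI-1 rose in mature green and fell in red ripe fruit, a difference of -7.66 ± 0.21, and cel5 and exp11 differed by -6.91 ± 0.15 and -6.42 ± 0.20. Of the ERF and WRKY genes 7 of 12 were higher and 3 lower, also when adjusted over the list alone (adjusted p = 0.00141, and adjusted p = 0.0285 with an estimated correlation), with PTI4 at 3.02 ± 0.11. Of 23 cell wall genes 0 were higher and 18 lower, also when adjusted over the list alone (adjusted p = 0.00805, and adjusted p = 0.276 with an estimated correlation), with Cel2 at -4.55 ± 0.12 and TBG6 at -3.41 ± 0.14. Of the ripening regulators and markers 10 of 15 were higher and 2 lower, also when adjusted over the list alone (adjusted p = 0.0277, and adjusted p = 0.102 with an estimated correlation), with the MADS-box gene TDR6 at 1.77 ± 0.10. The 3 epidermis genes were higher, also when adjusted over the list alone (adjusted p = 0.0415, and adjusted p = 0.313 with an estimated correlation), a call that ended on centring (adjusted p = 0.0511). The 17S control signal moved with these groups, from 6.67 ± 0.93 to 11.18 ± 1.81 on red ripe and from 5.08 ± 0.10 to 6.49 ± 1.42 on mature green wounding (SD, n = 3). PR1b1 differed by -5.43 ± 0.20 at its bright probe set and by -0.22 (adjusted p = 0.266) at the other. In all 5167 probe sets passed, 2542 higher and 2625 lower, 1665 of them at least 2-fold, 780 up and 885 down. Across probe sets the wound changes at the 2 stages correlated at r = 0.092 (Spearman 0.038).

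Inoculated fruit were also compared with healthy fruit, which joins the wound and the fungus. In mature green fruit CEVI-1 rose by 6.93 ± 0.13 (SE, n = 3 arrays per group; adjusted p = 2.05e-16), HT2 by 6.80 ± 0.09 and DES by 6.54 ± 0.16, and ARPI, THOM1 and DREB2 fell, by 2.43 ± 0.19, 1.75 ± 0.11 and 1.73 ± 0.11. The other THOM1 probe set, of mean level 3.23, gave -0.30 and did not pass (adjusted p = 0.057). Pathogenesis-related proteins rose as a list, 10 of 12 up and 0 down, and 11 and 1 adjusted over the list alone (adjusted p = 0.000261, and adjusted p = 0.0391 with an estimated correlation), with LOC543878 at 4.60 ± 0.12 and CHI17 at 2.34 ± 0.07. Ripening regulators and markers did not pass as a list against healthy fruit, with 4 of 15 up and 8 down, and 4 and 9 adjusted over the list alone (adjusted p = 0.275). The mean over the list was 0.19, while its median was -0.25 and its test pointed down. PG2 rose by 2.72 ± 0.12, ACS4 by 2.76 ± 0.10, ACS2 by 1.79 ± 0.08 and RIN by 0.58 ± 0.12. Psy1 fell by 0.32 ± 0.07, and its other probe sets gave -0.75 (adjusted p = 3.88e-05) and -0.02 (adjusted p = 0.934). E8 fell by 0.75 ± 0.09, and NOR gave -0.14 ± 0.16 and did not pass. The 25S control signal was 7.09 ± 0.09 in healthy and 8.29 ± 2.08 in inoculated fruit (SD, n = 3). A total of 4291 probe sets passed, 1807 higher and 2484 lower, 657 of them at least 2-fold, 498 up and 159 down. The changes correlated with those of ripening at r = 0.376 across probe sets (covariance 0.298), where 2 simulated unchanged groups against the shared healthy arrays gave r = 0.502 and a covariance of 0.0089. The simulated r follows from the shared reference alone and is no measure for the real r. By covariance the shared arrays added little. In both comparisons 1111 probe sets were higher, where independent lists would share 663.7, and 1139 lower, where they would share 686.8. Part of that excess may come from the shared arrays.

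In red ripe fruit AOS rose by 5.19 ± 0.11 over healthy fruit (SE, n = 3 arrays per group; adjusted p = 2.78e-15), THM16 by 4.96 ± 0.17 and ACS6 by 4.86 ± 0.07. PR1b1 fell by 5.30 ± 0.14 at its bright probe set, with -0.001 (adjusted p = 0.997) at the other, CHS2 by 4.35 ± 0.15 and ACS4 by 3.27 ± 0.10. Of the ERF and WRKY genes 9 of 12 rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.0141, and adjusted p = 0.08 with an estimated correlation), with EREB at 4.04 ± 0.14. Alongside these groups the 17S control signal was 6.67 ± 0.93 in healthy and 11.31 ± 0.95 in inoculated fruit, and the 25S signal 12.62 ± 0.89 and 13.65 ± 0.13 (SD, n = 3). Of the carotenoid genes 1 of 15 rose and 10 fell, also when adjusted over the list alone (adjusted p = 0.0395, and adjusted p = 0.178 with an estimated correlation), with DXS at -2.02 ± 0.06 and PDS at -1.61 ± 0.07. With the mean of each gene's probe sets the adjusted p was 0.0511. Of the 3 Psy1 probe sets 2 fell, by 0.75 (adjusted p = 4.91e-08) and 0.81 (adjusted p = 6.99e-06), and 1 rose, by 1.02 (adjusted p = 2.84e-06). In all 6074 probe sets passed, 2643 higher and 3431 lower, 1591 of them at least 2-fold, 770 up and 821 down. Centring each array on its median moved the changes of this comparison by 0.101 and turned the majority, to 3292 higher and 2863 lower, and changes of that size here depend on the scaling.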

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

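The tests of RNA quality, of a mislabelled array, of wounded fruit as the reference and of other splits of the arrays were chosen after the results were seen, and the tests of the differences between stages were planned.

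The response to inoculation differed between stages at 1804 probe sets. Changes were higher in red ripe fruit for Dea1 (5.17), ODC (3.85), sbt3 (2.54), Wfi1 (2.44), psi14A (2.21), HT1 (2.08), cel7 (2.03) and TSI-1 (1.95). They were lower in red ripe fruit for Man4 (-3.90), ACS4 (-3.64), PG2 (-3.50), TIP (-3.43), GluB (-3.36), cevi19 (-3.23), PTI5 (-2.97) and NOR (-2.93), and the ripening regulators and markers differed by -1.13 in the mean. Wounded fruit as the reference was not tested for these genes and stays open, as for sbt3 and TSI-1, which had fallen on red ripe wounding. With treatment exchanged within stages in 100 drawn splits, the real one included, 2 reached the real count: the real split and one that exchanges treatment wholly in 1 stage (2765), which turns the difference into a sum; the highest of the other splits gave 1062. These splits take treatment to have no effect at either stage. They cannot decide whether the response was equal at both stages, so no conclusion on the stage difference is drawn from them. For the correlation of the infection changes between stages, 3 of 100 splits, the real one included, reached the real 0.318 (highest other 0.333). Splits other than the real one thus gave values as large, and chance alone is not excluded there.

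The first pattern weighed is that genes of ripening moved in infected mature green fruit, the raised set by 0.496 and the lowered set by -0.301. By their choice the raised set has lower, and the lowered set higher, signal in healthy mature green than in healthy red ripe fruit. The signal range may add to both values, which was not tested. With the 25S signal as a covariate over the 9 mature green arrays, the raised set still lay 0.493 ± 0.023 (SE) above the others. The lowered set lay at -0.302 ± 0.026, and the signal accounted for 0.002 ± 0.007 and 0.001 ± 0.008. The changes of the sets thus did not follow the 25S signal within groups. Only 2 probe sets were called for that signal in the fit, so it followed few changes of any kind. The fit therefore cannot exclude RNA quality as a cause, which stays open. Wounded fruit as the reference is excluded as the whole cause for both sets, since with no healthy array shared the raised set moved up on wounding as well, by 0.278 or more, and the lowered set rose by 0.052 at most (largest SE 0.032), too little to account for its change. For the list of ripening regulators and markers that explanation fits: against healthy fruit the mean of the list was 0.194, so much of its rise over wounded fruit may be the recovery of a fall on wounding. The ERF and WRKY list and the ethylene list also fell on mature green wounding (camera adjusted p = 0.00333 and 0.00916). Against healthy fruit neither passed (camera adjusted p = 0.562 and 0.228), so the same may hold for their rises. With sets taken from wounded fruit and followed against healthy fruit the values were 0.171 and 0.114. On that same reference, sets taken from healthy fruit with the arrays parted gave 0.769 to 0.802 and -0.280 to -0.248. The values thus depend on how the sets are chosen. The mature green wound change enters the choice from wounded fruit and the change against healthy fruit with opposite signs. It works against the pattern in that check, by an amount not tested, so no conclusion on the pattern is drawn from it. An earlier onset of ripening in infected fruit, as a biological explanation, stays open and was not tested.

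The second pattern is the ripening difference together with the rRNA control signals, which were flagged as a signal outside the main measurement: 25S was 5.53 higher and 17S 1.59 higher in healthy red ripe than in healthy mature green fruit. Were RNA quality the cause, mature green arrays of high and low 25S signal within 1 group should differ as ripening does. For changes of at least 2-fold only 0.9% of probe sets did so by at least 0.5 of the ripening change. That argues against RNA quality as their whole cause, as far as the 25S signal follows it. The check compares arrays within groups of 3, so a single array stands against the rest, and scales 25S differences of 4.28 and 3.50 up to 5.53. The ef1a difference, 1.22 in healthy mature green and 2.50 in healthy red ripe fruit, was not put through it. RNA quality beyond the 25S signal stays open for these changes. The control signal differs between the stages themselves, which holds for changes of either size. For the 4489 called changes under 2-fold the share was 14.7%, and there RNA quality and ripening cannot be told apart. Small changes reach 0.5 of their size by noise more readily than large ones. The share expected from noise was not computed, so the difference between 0.9% and 14.7% is not read as an effect of RNA quality. The stage of the fruit, as a biological explanation, remains open for these as well.

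The third pattern is that the wound response differed between stages, at 5167 probe sets, with WRKYIId-1 (4.20), ACS6 (3.56) and ACO5 (3.24) higher, TSI-1 (-7.66), cel5 (-6.91) and exp11 (-6.42) lower, and ERF and WRKY factors 1.44 higher in the mean. Of 100 drawn splits with treatment exchanged within stages 1, the real one, reached this count (highest other 3129). As for infection, such splits cannot decide whether the response was equal at both stages. For red ripe wounding changes of at least 2-fold, arrays of high and low 17S signal within 1 red ripe group differed likewise at 8.3% of probe sets at most. That argues against RNA quality as the whole cause only as far as the 17S signal follows it. The 8.3% rests on a 17S difference of 1.54 between a single inoculated red ripe array and the other inoculated red ripe arrays, scaled to 4.50. The gapdh 3′ to 5′ difference, 1.242 in healthy and 0.605 in wounded red ripe fruit, was not put through this check. Of the 9 red ripe arrays 0 lay closest to an array of another group, which argues against a single misplaced array. An exchange of whole groups would not show in that check. A difference in fruit between the healthy and wounded red ripe pools was not tested and stays open, as does a wound response that depends on stage.

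For the comparisons of 3 against 3 arrays, and the 2 ripening sets in mature green infection, there are 10 splits, of which the real one is 1, too few for a share under 0.05. The real count and the highest other were 1971 and 2 for mature green infection, 2547 and 4 for red ripe infection, 6503 and 0 for ripening, 4168 and 0 for mature green wounding, 5412 and 1 for red ripe wounding, 4291 and 0 for mature green inoculated against healthy, and 6074 and 1 for red ripe inoculated against healthy fruit. For the sets the sizes were 0.496 and 0.204 (raised), and 0.301 and 0.140 (lowered).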

How the results depend on the processing

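The ef1a 3′ to 5′ covariate, leaving out mature green arrays of a 25S signal above 10, sets taken from wounded fruit and parted healthy arrays were chosen after seeing the data; the other alternatives were planned. By construction the ef1a covariate, taken within groups, left every log2 change as it was and altered only the error estimate. Its counts stayed within 1.5 times, but it cannot test the ef1a difference between groups. Counts of called probe sets also stayed within 1.5 times under the low-signal filter, centring, quantile normalization and the trended and robust prior. They moved further with array weights in mature green infection (3424), with the compared groups alone in red ripe infection (1594), and without the mature green arrays of high 25S signal in mature green infection (791), the infection difference (878) and mature green wounding (2321), where 1 wounded array is left and assumed to vary like the other groups; otherwise the cause was not tested. A 2-fold threshold left 310, 239, 448, 2014, 630, 1054, 1665, 657 and 1591, in the order mature green infection, red ripe infection, infection difference, ripening, mature green wounding, red ripe wounding, wounding difference, and inoculated against healthy fruit (mature green, red ripe). Leaving out each array in turn gave 1501 to 1735, 1979 to 2777, 1432 to 1910, 6050 to 6379, 3549 to 3826, 4994 to 5167, 4793 to 5171, 3670 to 3984 and 5683 to 5881 in that order, 0.465 to 0.515 for the raised set, -0.318 to -0.283 for the lowered set and 0.295 to 0.340 for the correlation between stages. Ripening gave 7691 from wounded and 7826 from inoculated arrays, with 518 and 688 of the shared calls reversed.

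Same-numbered arrays correlated at -0.40 to 0.25 (mean -0.01) and 4 of 18 correlated best with their own number; with that number as a block the counts were 1876, 2450, 1709, 6465, 4098, 5389, 5117, 4200 and 6025, and 27 of 28 list calls stayed. With the ripening sets taken from wounded fruit and followed in inoculated against healthy mature green fruit, the raised set gave 0.171 and the lowered set 0.114, which reversed. The mature green wound change enters that choice and the followed change with opposite signs, and how much this adds was not tested. The raised set gave 0.217 without a fold threshold, 0.969 for the 200 most changed probe sets, 0.824 against healthy fruit and 0.540 without the arrays of high 25S signal, and the lowered set -0.211, -0.438, -0.271 and -0.354, all in the same direction as before. The values against healthy fruit share the healthy mature green arrays with the choice of the sets. With these arrays parted they were 0.769 to 0.802 and -0.280 to -0.248. For the lowered set the camera p with an estimated correlation then reached 0.0599, so it did not pass in every parting. The correlation between stages was 0.224 against healthy fruit (SD over single arrays 0.059). Of 28 list calls 8 stayed with an estimated correlation, 26 after centring and 28 after quantile normalization; 20 were found with inoculated against healthy fruit. Values of named genes reversed at another probe set for ERF3 in mature green (-0.015) and red ripe infection (-0.487), for Psy1 in mature green infection (-0.103), red ripe infection (0.407), the infection difference (0.510), mature green wounding (0.087), red ripe wounding (0.612) and red ripe inoculated against healthy fruit (1.018), and for PR1b1 in mature green wounding (0.005); the cause was not tested. Of 3780 leave-one-out values of named genes 3648 kept their call, 100 were weaker, 13 stronger and 19 moved; with the block 510 of 513 kept it and with centring 499. The alternative for linear values was not run, as the values are log2. The number of arrays and, for probe sets near the lowest signal, signal over background limit precision.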

Other observations

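No test in this part was chosen after its result was seen; the lists were fixed beforehand, and none of those below passed as a list. Of the jasmonate biosynthesis list 6 of 8 genes rose and 1 fell in mature green wounding, and 7 and 1 adjusted over the list alone (adjusted p = 0.0978). Among them were loxD at 2.26 ± 0.11 (log2 ± SE, n = 3 arrays per group) and the reductase opr2 at 1.43 ± 0.10. In red ripe wounding 4 rose and 3 fell, and 4 and 4 adjusted over the list alone (adjusted p = 0.489). Infection added 3 rises and 2 falls in mature green (adjusted p = 0.562) and the same number in red ripe fruit (adjusted p = 0.349), with 4 and 2, and 3 and 2, adjusted over the list alone. AOS rose by 1.18 ± 0.11 and 2.28 ± 0.11, loxD by 1.08 ± 0.11 and 0.98 ± 0.11, while the desaturase Fad7 fell by 0.67 ± 0.08 and 0.75 ± 0.08. Of 7 wound- and jasmonate-inducible defence proteins 4 rose and 0 fell in mature green infection, also when adjusted over the list alone (adjusted p = 0.0967): CEVI57, the aminopeptidase LAPA1 (1.51 ± 0.18), the threonine deaminase TD2 (1.12 ± 0.17) and ARG2 (0.86 ± 0.18, with 0.95 and 0.36 at its other probe sets, the latter not past the test). In red ripe infection only CEVI57 rose, also when adjusted over the list alone (adjusted p = 0.275).

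Sugar metabolism genes went both ways in infection, with 3 of 16 up and 2 down in mature green (adjusted p = 0.536) and 5 up and 5 down in red ripe fruit (adjusted p = 0.556), in both also when adjusted over the list alone. The invertase gene Wiv-1 rose on infection in both stages and lin5 by 2.23 ± 0.13 in mature green fruit; Wiv-1 had risen by 4.28 ± 0.08 on mature green wounding, and the change on red ripe wounding differed from it by -5.29. Of 12 redox genes 4 rose and 1 fell in mature green infection (adjusted p = 0.254) and 0 rose and 2 fell in red ripe infection (adjusted p = 0.482), in both also when adjusted over the list alone; the alternative oxidase AOX1a rose by 1.02 ± 0.09 in the former and by 4.13 ± 0.09 on ripening. Of 5 phenylpropanoid genes 0 rose and 1 fell in mature green (adjusted p = 0.243) and 0 rose and 2 fell in red ripe infection (adjusted p = 0.275), in both also when adjusted over the list alone; CHS2 had risen by 2.19 ± 0.15 on mature green wounding and fell by 1.28 ± 0.15 on red ripe wounding. Of 3 isoprenoid genes 1 rose in mature green (adjusted p = 0.223) and 2 in red ripe infection (adjusted p = 0.158), in both also when adjusted over the list alone, with the farnesyl diphosphate synthase FPPS1 at 1.13 ± 0.07 and 0.82 ± 0.07. The small heat shock protein HSP21 fell by 0.93 ± 0.07 in mature green infection and rose by 1.23 ± 0.07 on mature green wounding, and vis1 rose by 4.05 ± 0.09 on ripening. Wounding raised 549 probe sets in both stages, where independent lists would share 459.9, and lowered 812 in both, where they would share 666.1. It also raised 620 in mature green and lowered them in red ripe fruit (542.1), and the reverse held for 607 (565.1).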
